A study of Sus scrofa with 24 samples.

How the data were processed

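RNA from pooled pig embryos at day 30 of gestation was hybridized to two-colour arrays. Per the labels, 6 control sows and 3 sows of each strategy gave a female and a male pool each of 3 embryos, RNA was taken with a column kit, and 200 ng was labelled with an Agilent low input kit with spike-ins. The labels name 24 pools, so each replicate has a control pool of its own by that count. Female and male pools were kept apart, and each replicate was measured on 2 arrays with exchanged dyes. The labels number replicates 1 to 3 in every group but do not say whether a female and a male pool with the same number came from the same sow.

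The deposited table holds a log ratio of both channels for 43749 probes on 24 arrays, taken here as log2. The authors' log base, normalization, background correction and filter are not given in the sources used here. The base was set from the range of the deposited values, which run from -9.34 to 9.85, too far for log10. Medians of the arrays lay within 0.05 of 0, and 16.6% of values were blank. SDs ran from 0.620 to 0.890 on female arrays and from 0.937 to 1.33 on male arrays, without overlap. Medians ran from -0.0014 to 0.036 on female arrays and from -0.048 to -0.013 on male arrays. Sex therefore goes together with the scale of the arrays. The fits nevertheless shared a common spread over both sexes, and contrasts between sexes compare arrays of unlike scale. Signal intensities were not used here, so no filter on signal over background could be set. Whether columns hold Cy5 over Cy3 or the opposite is not stated. Columns were taken to run in dye order. The 2 arrays of a replicate correlated below 0 in 7 of 12 pairs as deposited (Spearman's rho across 18481 complete probes from -0.298 to 0.324), namely in 6 of 6 male but 1 of 6 female pairs, in 10 with each probe's mean over the arrays removed and in 12 with its mean within a sex removed. The last step by itself pulls correlations below 0, so the labelled pairs were compared with all 720 pairings of the 6 arrays of each orientation in a one-sided exact permutation test. The labelled pairs had a mean rho of -0.244 in females (other pairs -0.148; exact p = 0.0444) and -0.406 in males (other pairs -0.089; exact p = 0.00139). The labelled partner had the lowest rho for 2 of 6 female and 5 of 6 male arrays, so the order is less certain for female pools. Arrays with the control RNA in Cy5 were therefore multiplied by -1, which fixes the ratios up to a common sign if all columns run in dye order. The rule set before the data were examined changed no sign where the 2 arrays correlate above 0. As deposited, only 1 of 6 female pairs lay below 0, so for female pools the choice rests on the means removed afterwards. If female columns were already turned, effects in female pools would cancel in the mean of both arrays. An alternative without the turn was not run.

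Probes were given gene symbols from the platform's annotation, brought up to date with reference tables by accession or synonym. A single symbol was found for 18109 probes and none for 25640, which gave 11902 symbols, 878 of them only locus identifiers. Of 4738 accessions 2657 were found in the reference table, 103 probes were renamed by accession and 224 by synonym, and 3 kept a symbol that is in no table. No genome coordinates were used. The 2 arrays of a replicate were averaged where both were measured, and the probes of a gene were averaged. The average took the probes measured in each replicate, so different probes of a gene can stand behind different replicates.

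Each comparison was tested with limma 3.58.1 in R 4.3.3: a fit of the 4 group means on the 12 replicates, moderated with eBayes without trend, in genes with at least 2 measured replicates in each group concerned, and Benjamini-Hochberg adjustment with a threshold of 0.05. The 9 contrasts were the 4 groups against control, the mean of both sexes for each strategy, the difference between sexes for each strategy and the difference between strategies. Adjusted p values below are from limma unless another test is named. Named genes were, by a rule set before the data were examined, those past the threshold, and where fewer than 10 passed, those with the smallest p up to 10, given as values only and passing over symbols that are only locus identifiers. In addition, genes of the lists are named that passed when adjusted over the list alone, or that had the smallest p of a list past its threshold.

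There were 29 lists of genes for organs, cell types, growth, stress and metabolism, written before the data were examined. They were tested with limma's camera with a preset correlation of 0.01, with an estimated correlation, on ranks, and with fry, on the 6528 genes measured in all 12 replicates. None of the calls with the preset correlation held with an estimated correlation in any of the 9 contrasts, and fry called 0 lists in each. Benjamini-Hochberg adjustment ran over the lists of a contrast. Lists of a given contrast also had an exact two-sided sign-flip test over replicates, whose smallest p is 0.25 with 3 replicates and 0.0312 with 6. With 6 it takes female and male pools as independent, so after the data were seen it was repeated with the 3 sows of a strategy as units, over every pairing of their pools. The same sows stand behind the fits of the mean of both sexes, for which the replicate block is an alternative.

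Alternatives set before the data were examined were centring and scaling of arrays, filters on blanks and on genes with small ratios, the median of probes, array weights, robust moderation, arrays of a single dye orientation, a fit to the 24 arrays with a dye term and the replicate as random block, groups fitted apart, other thresholds, the replicate number as a random or fixed block, and leaving out each replicate. Several choices were made after the data were seen: the minimum of 2 replicates, which was set after a first look without a minimum had called 1 probe, the demand for both arrays of a replicate, the restriction of list tests to complete genes, list tests of the 3 difference contrasts, and the means removed before dye-swapped arrays were correlated. Before these settings were fixed, probes had been tested, genes and lists had been tested, and orientation had been examined, each in an earlier look. With the 27 lists of at least 3 measured members in place of all 29, the endothelium list for the mean effect of IS21FE had an adjusted p of 0.0496 in place of 0.0532; all 29 were kept. Alternatives added after the data were seen were genes with 1 measured replicate, replicates with 1 measured array, the 27 lists, and a term for, or removal of, 3 arrays that resembled each other.

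The pipeline was tested on simulated data for each comparison, with normal noise of each gene's residual spread, the blanks of the real data, and 200 genes changed, 50 at each fold size. The share of genes recovered at 1.5-fold, 2-fold, 4-fold and 8-fold was 30%, 58%, 70% and 92% for female IS21FE (9800 genes), 42%, 68%, 88% and 94% for male IS21FE (9804 genes), 44%, 64%, 80% and 92% for female IS21SE (9819 genes), and 24%, 60%, 86% and 88% for male IS21SE (10133 genes), with 0 calls where no gene was changed. With the 200 genes changed, false calls were 10 of 135 in female IS21FE and 4 of 150 in male IS21FE. They were 6 of 146 in female IS21SE and 6 of 135 in male IS21SE. The simulated noise was independent between genes, held no dye effect and had the same spread in female and male pools, unlike the real arrays. The share recovered at a fold size also depends on the larger changes adjusted together with it. In the real data the median standard error of a ratio was 0.189, 0.187, 0.187 and 0.191 in the same order. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.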

Results

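Gene expression was measured in pools of pig embryos at day 30 of gestation. The embryos came from primiparous sows, which had farrowed a single time, either under a control treatment or under a strategy of intermittent suckling and mating that the labels call IS21FE or IS21SE without spelling out the letters. Each two-colour array compared a treated pool with a control pool of the same sex, with 3 embryos in a pool. The 24 arrays formed 4 groups (female IS21FE, male IS21FE, female IS21SE and male IS21SE, each against control) of 3 biological replicates, and each replicate was hybridized on 2 arrays with the dyes exchanged. The array table held 43749 probes. Between 31722 and 39435 of them had a value on an array, and the number of arrays limits the precision of every ratio. All values are log2 ratios turned so that treated pools stand over control pools if the deposited columns hold Cy5 over Cy3. The files do not state that order, so ratios are described as positive or negative. That the columns run in dye order at all is less certain for female pools. A positive ratio means more RNA in the treated pool under Cy5 over Cy3, and less under the opposite order.

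The comparison of female IS21FE pools with control asked which genes differ in female embryos of sows under IS21FE. The gene with the smallest p was SKIL, a repressor of TGF-beta signalling, with a ratio of 0.70 ± 0.20 (SD, n = 3). PIK3R1, a regulatory subunit of phosphoinositide kinase, had -0.80 ± 0.11 (SD, n = 2). COL8A2, a collagen chain, had -0.86 ± 0.16 (SD, n = 3), and COPA, a subunit of the vesicle coat, had -0.53 ± 0.14 (SD, n = 3). PDZD2 had 1.29 (n = 2), DDX51 0.86, FBXL8 0.79, ZKSCAN2 0.63 and RIMKLA 0.61 (n = 3 each). TERF2, a telomere-binding protein, had -0.74 (n = 2). In the limma fit 0 of 9800 genes passed an adjusted p of 0.05, and the adjusted p of these 10 genes was 0.497. At an unadjusted p under 0.05 there were 783 genes, 462 positive and 321 negative, where chance gives 490. The count depended on single replicates: it was 385 of 8759 genes without replicate 1, 790 of 8039 without replicate 2 and 403 of 7962 without replicate 3. With array weights it was 1845 of 9800. Among 32637 probes limma also called 0, with 2659 at an unadjusted p under 0.05. The fit to the single arrays with a dye term called 1 gene, PIK3R1 (adjusted p = 0.00254), and 0 with a further term for 3 arrays that resembled each other (lowest adjusted p = 0.113) or without those arrays (0.823). Here and below, that fit counts the 2 arrays of a replicate, which hold the same RNA, as nearly independent (correlation -0.0452). When 200 genes were changed in simulated data of this comparison, 58% of those changed 2-fold and 70% of those changed 4-fold were recovered.

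In female IS21FE pools 3 gene lists fixed before the data were examined lay on the negative side of the other genes. Of 44 ribosomal protein genes 36 were negative, with a mean of -0.080, and RPL10A (-0.22, n = 3) and RPLP2 (-0.22, n = 3) had the smallest p. The list passed camera with its preset correlation (adjusted p = 8.67e-07), with 2 of 3 replicates negative, but not with an estimated correlation (adjusted p = 0.745). On the arrays with the treated RNA in Cy5 its mean was 0.051, on the other side of 0. Of 29 genes of the extracellular matrix 20 were negative, with a mean of -0.10 in 3 of 3 negative replicates (adjusted p = 0.00119; adjusted p = 0.745 with an estimated correlation). Its members included the collagen chains COL1A2 (-0.35 ± 0.12) and COL6A3 (-0.94 ± 0.97) and the proteoglycan DCN (-0.28 ± 0.11, SD, n = 3). Of 16 skeletal muscle genes 11 were negative, with a mean of -0.094 in 3 of 3 negative replicates (adjusted p = 0.0146; adjusted p = 0.745 with an estimated correlation). The muscle enolase ENO3 had -0.63 ± 0.62, and the contractile genes MYLPF and MYBPC1 had -0.24 ± 0.058 and -0.26 ± 0.048 (SD, n = 3). The myogenic regulators MYOD1 (0.28) and MYOG (0.22) had positive ratios. Adjusted over the list alone, 0 members of these 3 lists passed, and over all genes 0 passed. Without replicate 3 the matrix list (-0.11, adjusted p = 0.0566) and the muscle list (-0.10, adjusted p = 0.0814) no longer passed, and without replicate 1 the ribosomal mean was -0.042 (adjusted p = 0.0105), against -0.14 without replicate 2. From arrays with the treated or the control RNA in Cy5 alone, neither the matrix list (-0.091 and -0.12) nor the muscle list (-0.13 and -0.065) passed. A group of 3 arrays with the treated RNA in Cy5 resembled each other (female IS21FE replicates 1 and 3 and female IS21SE replicate 2; Spearman's rho from 0.559 to 0.614 across probes, which are not independent replicates). Without those arrays the ribosomal mean was -0.079 (adjusted p = 0.0556).

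Among the other lists in female IS21FE pools, 4 genes passed when adjusted over the list alone and 0 over all genes. DIO3, an imprinted deiodinase that inactivates thyroid hormone, had -1.36 ± 0.52 (SD, n = 3; adjusted p = 0.019 over 24 imprinted genes). HSD17B1, a dehydrogenase of oestrogen synthesis, had -0.72 ± 0.095 (SD, n = 3; adjusted p = 0.0338 over 19 genes of the gonad and 0.0302 over 17 of trophoblast and endometrium). BMP2, a growth factor of limb and heart development, had 0.69 ± 0.48 (SD, n = 3; adjusted p = 0.0488 over 30 signalling genes). EIF1AY, the single measured gene of the list for checking sample sex, had 0.27 ± 0.045 (SD, n = 3), and its list holds no other measured gene to adjust over. Its p is thus unadjusted. These genes, like the list members named in the other comparisons, were chosen after their values were seen.

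In the comparison of male IS21FE pools with control, the largest ratio among the 10 genes with the smallest p belonged to GAS8, a component of the ciliary axoneme, at 2.40 ± 0.39 (SD, n = 3). GRAP2, an adaptor of T cell signalling, had -1.53 ± 0.19 (SD, n = 3). PRL, which encodes prolactin, had 1.62 ± 0.0036 (SD, n = 2), and the muscle gene ASB15 had 1.66 ± 0.064 (SD, n = 2). MBD1, a methyl-CpG binding protein, had -0.85 ± 0.32 (SD, n = 3), with its 3 probes between -2.03 and -0.31. SLC35B4 (-1.33), PRKG2 (-1.05) and EPB41L1 (-0.73) were negative, and PLEK (0.78) and PHTF2 (0.62) were positive, although the 2 probes of PHTF2 gave -0.043 and 1.29. In the limma fit 0 of 9804 genes passed, with adjusted p from 0.147 to 0.272 for these 10 genes. At an unadjusted p under 0.05 there were 630 genes, 274 positive and 356 negative, where chance gives 490. That count was 446 with the group fitted apart from the others, which is below 490, and 506 with array weights. Of 31761 probes limma called 0, with 2030 at an unadjusted p under 0.05. The fit to the single arrays with a dye term also called 0 genes, with 901 at an unadjusted p under 0.05, and in simulated data of this comparison 68% of genes changed 2-fold were recovered.

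The skeletal muscle list lay on the negative side in male IS21FE pools, with 15 of its 16 genes negative and a mean of -0.19 in 3 of 3 negative replicates. It passed camera (adjusted p = 0.000334) and not with an estimated correlation (adjusted p = 0.912). The sarcomere genes ACTN2 (-0.29 ± 0.25), MYL1 (-0.22 ± 0.080) and ACTC1 (-0.28 ± 0.32) and the enolase ENO3 (-0.48 ± 0.32; SD, n = 3 each) had the smallest p. Adjusted over the list alone, 0 members passed. Without replicate 1 the mean was -0.13 and the list no longer passed (adjusted p = 0.238), and with the control RNA in Cy5 alone it was -0.18 (adjusted p = 0.069). MBD1 passed when adjusted over the list alone among 26 regulators of DNA methylation and chromatin (adjusted p = 0.00367). HOXD13, a patterning gene of the distal limb, passed among 21 HOX genes (1.13 ± 0.0071, SD, n = 3; adjusted p = 0.039), but its ratio was -0.78 on the arrays with the treated RNA in Cy5 alone.

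**Figure D1:**
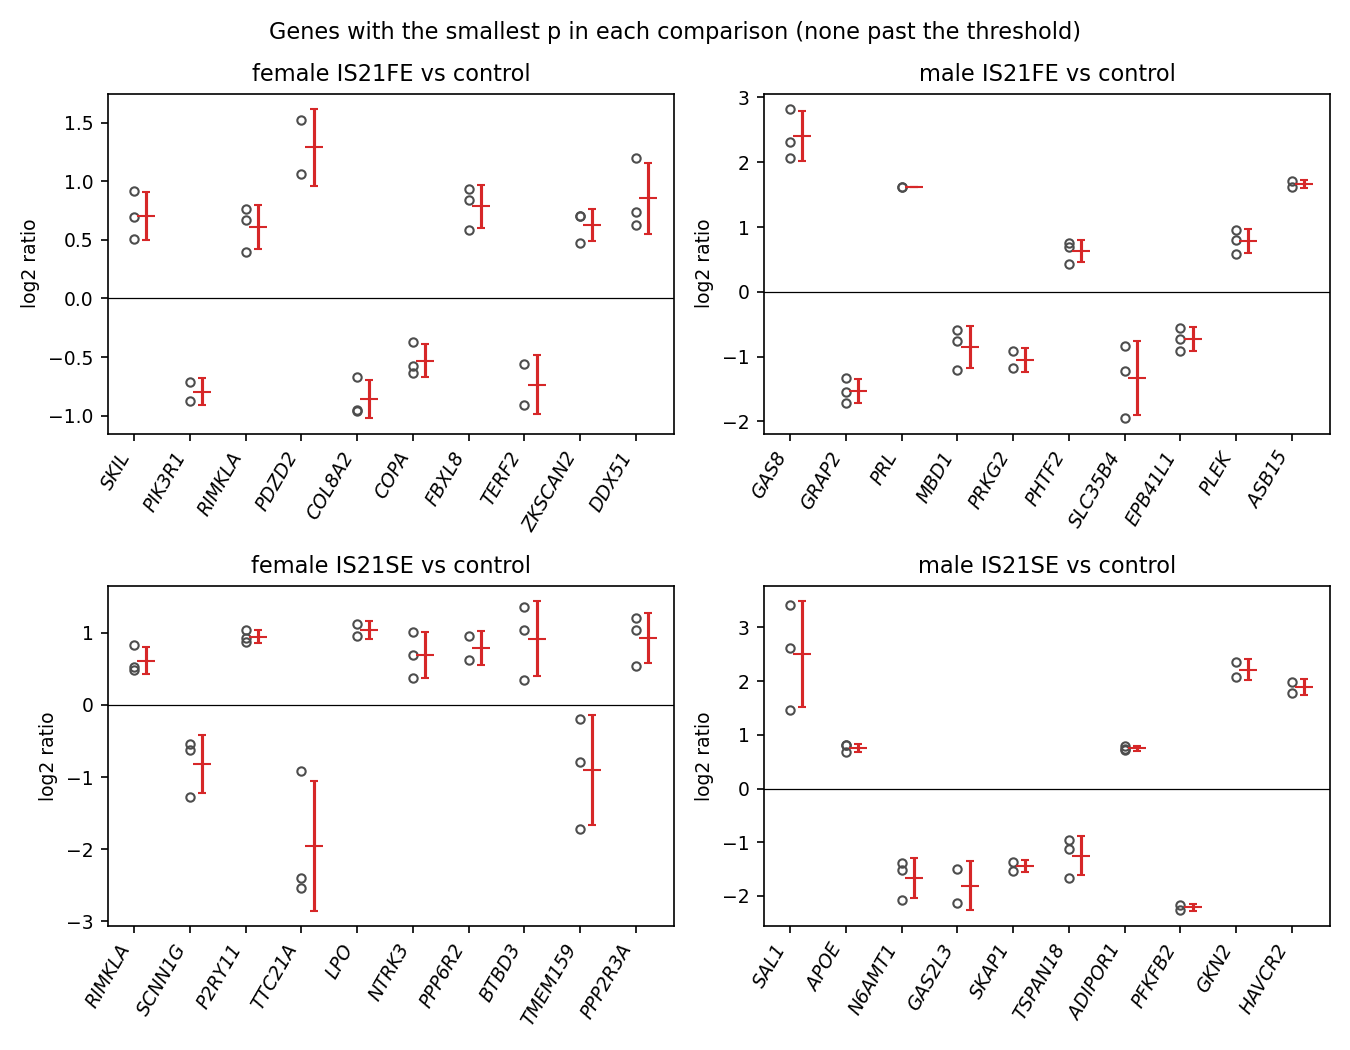
Log2 ratio to control of the 10 genes with the smallest p in each of the 4 comparisons, with points for replicates (means of 2 dye-swapped arrays) and bars for their mean and SD. GAS8 in male IS21FE pools (2.40) and SAL1 in male IS21SE pools (2.50) lie highest; 0 genes pass an adjusted p of 0.05, and the sign holds if columns are Cy5 over Cy3.

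In the comparison of female IS21SE pools with control, RIMKLA, an enzyme of dipeptide synthesis in the nervous system, had the smallest p, with a ratio of 0.61 ± 0.19 (SD, n = 3). TTC21A had -1.95 ± 0.90, although its 2 probes gave -2.93 and -0.18. SCNN1G, a subunit of the epithelial sodium channel, had -0.81 ± 0.40, and on the arrays with the treated RNA in Cy5 alone it had 0.021. P2RY11, a purine receptor, had 0.95 ± 0.087 (SD, n = 3), and LPO, which encodes lactoperoxidase, had 1.04 ± 0.13 (SD, n = 2). NTRK3 (0.69), PPP6R2 (0.79), BTBD3 (0.92) and PPP2R3A (0.93) were positive and TMEM159 (-0.90) was negative. In the limma fit 0 of 9819 genes passed, and the adjusted p of all 10 was 0.997. At an unadjusted p under 0.05 there were 459 genes, 277 positive and 182 negative, below the 491 that chance gives. That count was 300 of 8657 genes without replicate 1, 533 of 8556 without replicate 2 and 417 of 8800 without replicate 3. With array weights it was 817 of 9819, above chance, with replicate 2 weighted lowest (0.499, against 1.17 and 1.7 for replicates 1 and 3). Whether the count lies below or above chance thus depends on the weighting of single replicates. Of 32526 probes limma called 0, with 1534 at an unadjusted p under 0.05. The fit to the single arrays with a dye term called 0 genes, with 504 at an unadjusted p under 0.05. None of the 29 lists passed camera, and the lowest adjusted p was 0.663. GHR, the growth hormone receptor, passed when adjusted over the list alone among 18 genes of the insulin and growth hormone axis (-1.06 ± 0.73, SD, n = 3; adjusted p = 0.0367). Over all genes its adjusted p was 0.997, and a single such gene among 29 lists can arise by chance. In simulated data of this comparison 64% of genes changed 2-fold were recovered.

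In the comparison of male IS21SE pools with control, SAL1, a salivary lipocalin, had the largest ratio among the 10 genes with the smallest p, 2.50 ± 0.98 (SD, n = 3). APOE, a lipid carrier made in the liver and other tissues, had 0.76 ± 0.076 (SD, n = 3), with its 3 probes between 0.64 and 0.96. ADIPOR1, a receptor of adiponectin, had 0.75 ± 0.042 (SD, n = 3), with 3 probes between 0.34 and 1.05. The methyltransferase gene N6AMT1 had -1.66 ± 0.37 and TSPAN18 had -1.25 ± 0.37 (SD, n = 3). With 2 measured replicates each, GAS2L3 had -1.81, SKAP1 -1.45, PFKFB2, which controls glycolysis, -2.21, GKN2, a stomach protein, 2.21 and HAVCR2, an immune receptor, 1.89. On the arrays with the control RNA in Cy5 alone SKAP1 had 0.41, and with the treated RNA in Cy5 alone GKN2 had -0.60. In the limma fit 0 of 10133 genes passed, with adjusted p from 0.208 to 0.212 for these 10 genes. At an unadjusted p under 0.05 there were 1154 genes, 610 positive and 544 negative, where chance gives 507. That count was 766 of 9394 genes without replicate 1, 787 of 9302 without replicate 2 and 849 of 9413 without replicate 3. Of 33318 probes limma called 0, with 3719 at an unadjusted p under 0.05 and a lowest adjusted p of 0.099. The fit to the single arrays with a dye term called 4 genes, SAL1, APOE, MIOX and NPPA, and without replicate 1 the limma fit called 3, CEP135, IQCD and a gene with only a locus identifier. The 4 calls count the 2 arrays of a replicate as nearly independent, and in the limma fit to the 3 replicates SAL1 and APOE had an adjusted p of 0.208. In simulated data of this comparison 60% of genes changed 2-fold were recovered.

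Male IS21SE pools had 2 lists on the positive side. All 9 heart muscle genes in the set test were positive, with a mean of 0.41 in 3 of 3 positive replicates (camera adjusted p = 0.000373; adjusted p = 0.985 with an estimated correlation). Over all genes 0 of the list's 15 tested members passed, and adjusted over the list alone 5 passed. These were the natriuretic peptide genes NPPA (0.83 ± 0.19) and NPPB (0.98 ± 0.20), the myosin light chains MYL3 (0.60 ± 0.41) and MYL7 (0.61 ± 0.41; SD, n = 3 each), and the calcium channel gene RYR2, which was negative (-1.39 ± 0.94, SD, n = 2). Of 28 liver genes 25 were positive, with a mean of 0.30 in 3 of 3 positive replicates (camera adjusted p = 2.31e-05; adjusted p = 0.985 with an estimated correlation). The liver products PLG (0.50 ± 0.25), APOA1 (0.56 ± 0.080) and HPX (0.56 ± 0.46; SD, n = 3 each) were positive, APOA4 (-1.49 ± 0.20, SD, n = 2) was negative, and adjusted over the list alone APOE passed (adjusted p = 0.00243). Without replicate 2 the heart muscle mean was 0.24 and the list no longer passed (adjusted p = 0.149). Adjusted over the list alone, 4 genes of other lists passed. They were ENG, a receptor of endothelial cells (0.61 ± 0.097), the calcium-binding protein gene CALB1, from the kidney list (-0.76 ± 0.12), the histocompatibility gene SLA-3 (-0.88 ± 0.68) and the mitochondrial gene ND1 (0.65 ± 0.65; SD, n = 3 each), the last as the single measured member of its list.

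**Figure D2:**
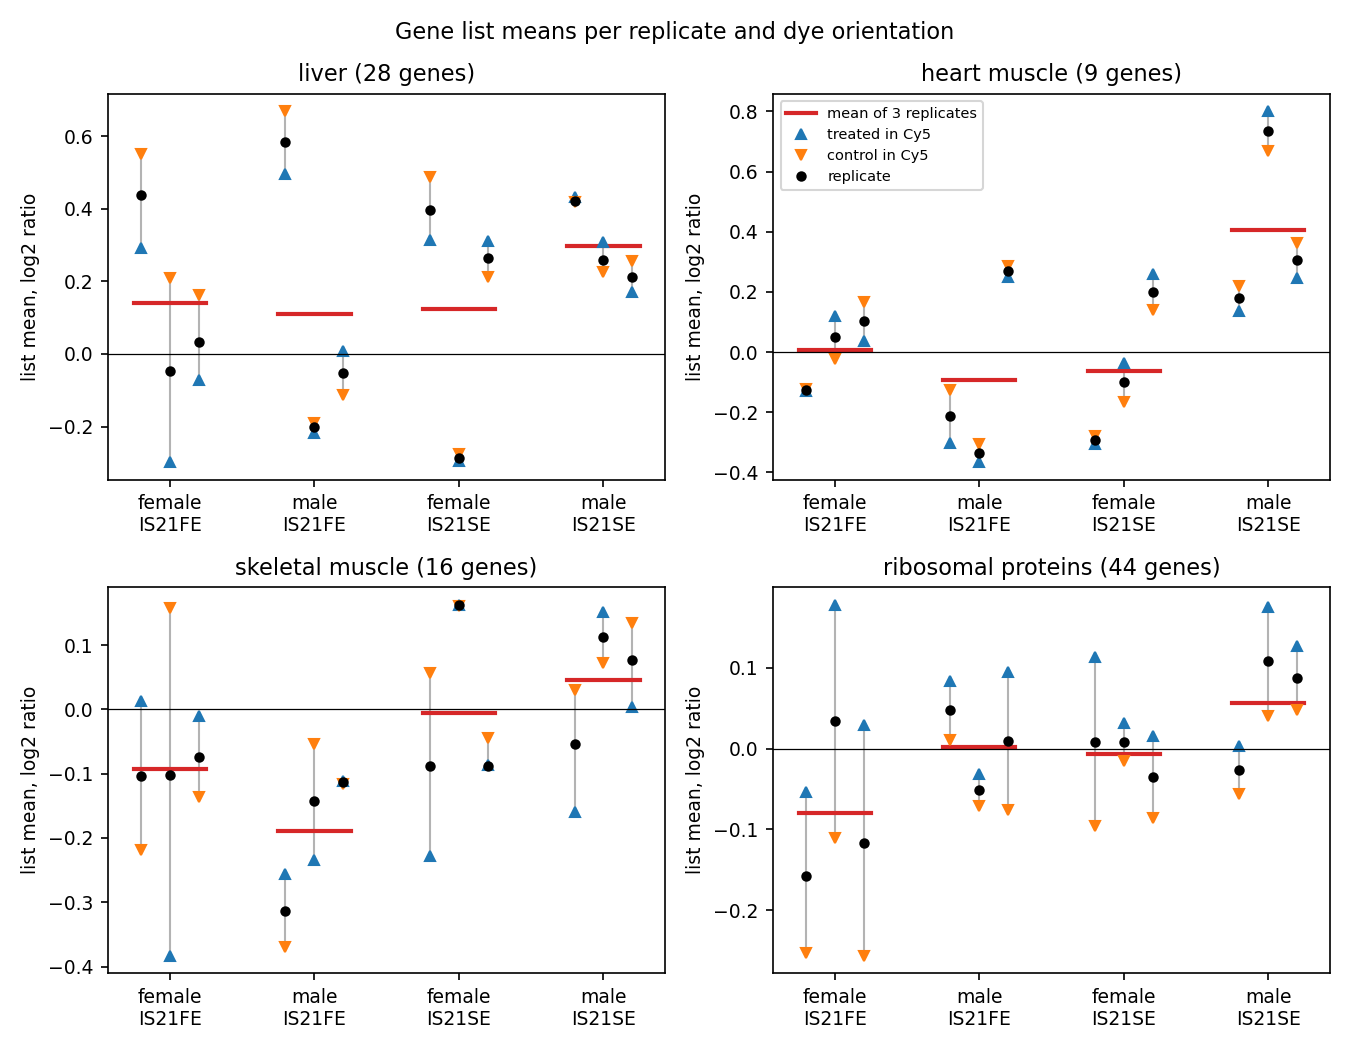
Mean log2 ratio of the members of 4 gene lists in each replicate, with separate points for the arrays with the treated RNA in Cy5 and those with the control RNA in Cy5. Heart muscle and liver means of male IS21SE pools lie above 0 in both orientations (heart 0.14 to 0.80, liver 0.17 to 0.43); ribosomal means in female IS21FE pools differ between orientations.

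Averaged over both sexes, IS21FE gave the smallest p for GRAP2 (-1.15 ± 0.12, SE, n = 5), followed by CD72, a B cell receptor (0.56 ± 0.098, SE, n = 6). PDZD2 (0.84), SLC28A2 (0.54), LUC7L3 (0.40), GPRC5B (0.80), PHTF2 (0.37, with probes at -0.073 and 0.81) and SKIL (0.42) were positive, and RASGEF1A (-0.86) and the integrin chain ITGA1 (-1.42) were negative. In the limma fit 0 of 8998 genes passed, with adjusted p from 0.375 to 0.577 for these 10 genes, and 665 had an unadjusted p under 0.05 where chance gives 450. With 1 replicate left out that count ran from 415 of 8313 genes (female replicate 1) to 660 of 8502 (male replicate 2). Fitted to the single arrays with a dye term, which counts the 2 arrays of a replicate as nearly independent, 2 genes passed, CD72 and LUC7L3. With a term for the 3 arrays that resembled each other 0 passed (lowest adjusted p = 0.0748), as without them (0.284). Skeletal muscle genes were negative in 13 of 16, with a mean of -0.14 (camera adjusted p = 5.18e-05; adjusted p = 0.945 with an estimated correlation). The list mean was negative in 6 of 6 replicates (exact two-sided sign-flip p = 0.0312 before any adjustment over lists). That test takes the 6 replicates as independent, but the female and male pools came from the same 3 sows. With sows as units p is 0.25, the smallest possible, for each of the 6 ways to pair the pools. ENO3 (-0.56 ± 0.16), MYLPF (-0.20 ± 0.066), ACTN2 (-0.23 ± 0.090) and MYBPC1 (-0.19 ± 0.076; SE, n = 6 each) were negative in 6 of 6 replicates, and adjusted over the list alone 0 members passed. Several of its genes, such as ACTC1, TNNC1 and ACTN2, are also expressed in heart muscle, and the list shares 0 genes with the heart muscle list. The ribosomal list (-0.039, negative in 3 of 6 replicates; adjusted p = 0.00676) and the matrix list (-0.069, negative in 5 of 6 replicates; adjusted p = 0.0125) passed as well, each with an adjusted p of 0.953 with an estimated correlation and 0 members adjusted over the list alone. Both lost their call without some replicates: the ribosomal mean was -0.020, -0.030 and -0.026 without female replicates 1 and 3 and male replicate 2, and the matrix mean was -0.051, -0.072, -0.049 and -0.052 without female replicates 2 and 3 and male replicates 1 and 2. With the treated RNA in Cy5 alone the ribosomal mean was 0.050 and the matrix mean -0.075 (adjusted p = 0.299 each), and with the control RNA in Cy5 alone the matrix mean was -0.065 (adjusted p = 0.493) and the muscle mean -0.12 (adjusted p = 0.0531). Without the 3 arrays that resembled each other the ribosomal mean was -0.039 (adjusted p = 0.43).

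Averaged over both sexes, IS21SE gave the smallest p for SKAP1, an adaptor of T cells (-1.03 ± 0.10, SE, n = 5), and GAS2L3, a protein that links the cytoskeleton (-1.36 ± 0.14, SE, n = 4). SAL1 (1.21), RHOF (0.45), PRSS23 (0.44), CALCB (0.39), RIMKLA (0.37) and JMJD8 (0.35) were positive, and PFKFB2 (-1.15) and ASAP2 (-1.18) were negative. The 2 probes of RHOF that could be tested gave smaller ratios, 0.152 and 0.365. On the arrays with the control RNA in Cy5 alone SKAP1 had 0.14 and CALCB had -0.026. In the limma fit 0 of 9195 genes passed, with adjusted p from 0.381 to 0.585 for these 10 genes, and 701 had an unadjusted p under 0.05 where chance gives 460. With 1 replicate left out that count ran from 428 of 8364 genes (female replicate 1) to 860 of 8288 (female replicate 2). With the single arrays and a dye term 0 genes passed, with 1031 at an unadjusted p under 0.05. Liver genes were positive in 26 of 28, with a mean of 0.21 (camera adjusted p = 0.00011; adjusted p = 0.94 with an estimated correlation) in 5 of 6 positive replicates (exact two-sided sign-flip p = 0.156, and from 0.25 to 0.5 with the 3 sows as units). Adjusted over the list alone 3 of 29 members passed: PLG (0.40 ± 0.10, SE, n = 6), APOE (0.34 ± 0.084, SE, n = 6) and, negative, APOA4 (-1.24 ± 0.20, SE, n = 4). Without female replicate 3 the liver mean was 0.18 and the list no longer passed (adjusted p = 0.0506), with the control RNA in Cy5 alone it was 0.22 (adjusted p = 0.0667), and without female replicate 2 and female replicate 1 it was 0.31 and 0.14.

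The difference between the sexes in the effect of IS21FE, female minus male, had the smallest p for GAS8 (-3.01 ± 0.37, SE, n = 6). PRKG2 (1.42), DDX51 (1.38), SCAMP3 (1.35), ZNF652 (1.5) and MBD1 (0.98) had positive differences, and DIO3 (-2.56), ASB15 (-2.31), PIK3R1 (-1.01) and HOOK1 (-1.23) had negative differences. The 2 probes of MBD1 that could be tested gave smaller differences, 0.255 and 0.662. HOOK1 had 0.13 on the arrays with the treated RNA in Cy5 alone. In limma 0 of 8998 genes passed, with adjusted p from 0.357 to 0.724 for these 10 genes and 500 at an unadjusted p under 0.05 where chance gives 450. With 1 replicate left out that count ran from 276 of 7592 genes (female replicate 3) to 574 of 8413 (male replicate 1). Fitted to the single arrays with a dye term, PIK3R1 passed (adjusted p = 0.00699), but not with a term for the 3 arrays that resembled each other (adjusted p = 0.0837) or without them (adjusted p = 0.632). For IS21SE the smallest p of the difference belonged to SAL1 (-2.58 ± 0.51, SE, n = 6) and APOE (-0.83 ± 0.17, SE, n = 6). HAVCR2 (-2.05), GPR21 (-2.57), PIK3R2 (-1.10) and ENG (-0.88) were negative as well, and the kinase gene LRRK2 (2.63), CLIP1 (1.57), TSPAN18 (1.40) and CCNC (0.61) were positive. No single probe of HAVCR2 was measured in at least 2 replicates of both sexes, so its difference rests in part on different probes. In limma 0 of 9195 passed, with an adjusted p of 0.578 for all 10 and 665 at an unadjusted p under 0.05 where chance gives 460, and the fit to the single arrays with a dye term called 0, with 896. Between the strategies, IS21FE minus IS21SE over both sexes, PHTF2 (0.69 ± 0.11, SE, n = 12) and GRAP2 (-1.38 ± 0.18, SE, n = 9) had the smallest p, although the 2 probes of PHTF2 gave -0.011 and 1.43. AMY2 (0.48), GNG12 (0.83), PLEK (0.60) and IFITM1, an interferon-induced gene (1.17), were positive, and DEAF1 (-0.44), TMED1 (-0.64), ANKFY1 (-1.46) and RIC8A (-0.45) were negative. In limma 0 of 8462 passed, with adjusted p from 0.679 to 0.97 for these 10 genes and 384 at an unadjusted p under 0.05, below the 423 that chance gives, and the fit to the single arrays called 0, with 647. Leaving 1 replicate out moved the limma count of 384 between 267 of 7312 genes (female IS21FE replicate 3) and 491 of 7908 (female IS21SE replicate 2). With array weights that count was 730 of 8462.

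Most gene lists did not pass camera in any of the 4 comparisons with control of a given sex. Imprinted genes (19 in the set test) had list means between -0.020 and 0.075 and adjusted p from 0.697 to 0.987, and markers of trophoblast and endometrium (11 genes) had means between -0.043 and 0.068 and adjusted p from 0.773 to 0.934. Neural genes (19) ranged from -0.051 to 0.069, HOX genes (10) from 0.0078 to 0.029 and cell cycle genes (21) from 0.016 to 0.086. Genes of the insulin and growth hormone axis (14) ranged from -0.12 to 0.056, oxidative phosphorylation genes (28) from -0.058 to 0.052, and genes of hypoxia and glycolysis (20) from -0.065 to 0.035. Erythroid genes (15) ranged from -0.058 to 0.13, with their lowest adjusted p in male IS21SE pools (0.0936). Of the sex-linked genes for checking sample sex only EIF1AY was measured. Both pools on an array had the same sex, so a ratio does not give the sex of a pool and the check could not be made. EIF1AY is given as values only. The EIF1AY ratios were 0.27 ± 0.045, -0.13 ± 0.24, 0.14 ± 0.13 and 0.0075 ± 0.13 (SD, n = 3 each) in female IS21FE, male IS21FE, female IS21SE and male IS21SE pools. Of 6528 genes measured in all 12 replicates, 11 had the same sign in all 12, where chance gives 3.19 if replicates are independent, which female and male pools of the same sows are not.

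**Figure D3:**
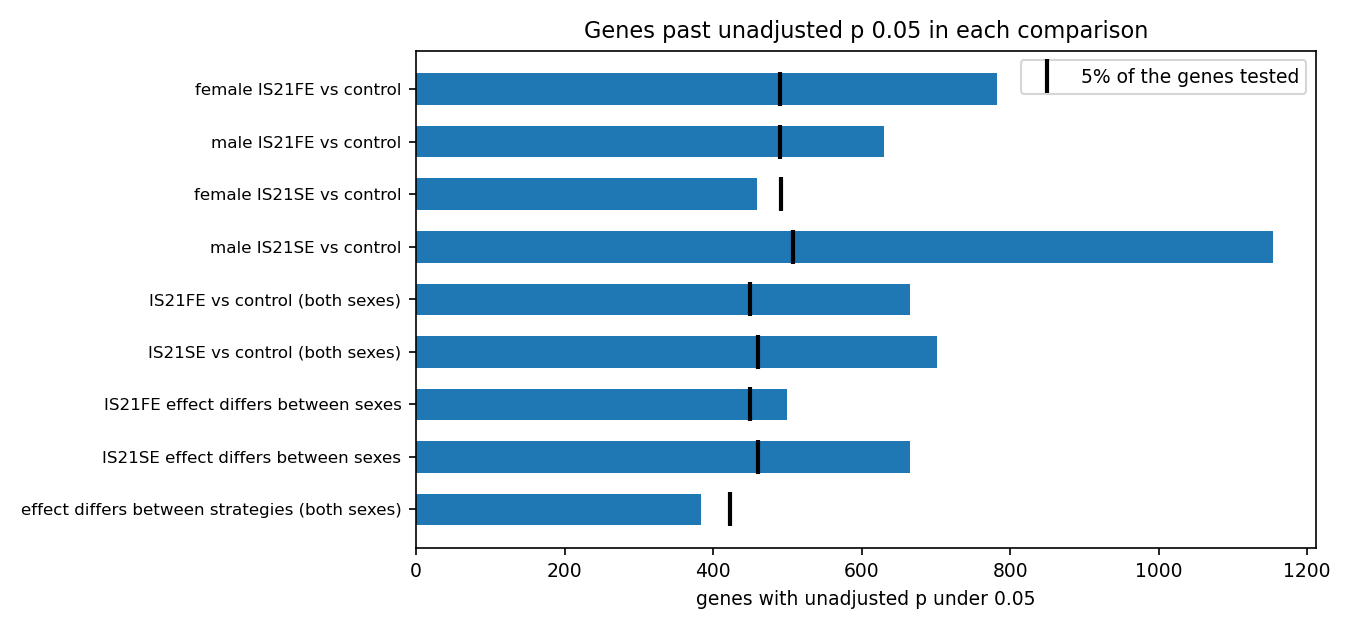
Number of genes with an unadjusted p under 0.05 in each of the 9 comparisons, beside the number chance gives. Male IS21SE pools had most (1154 against 507), and female IS21SE pools (459 against 491) and the difference between strategies (384 against 423) had fewer than chance gives. With 1 replicate left out (not drawn), these 3 counts ran from 766 to 849, 300 to 533 and 267 to 491. With array weights (not drawn) they were 1575, 817 and 730, all above chance.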

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

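The tests of dye bias, of pool differences and of the 3 arrays that resembled each other were chosen after the list values had been seen, as were the list tests of differences between sexes and strategies; the counts over other splits of the replicates were planned. The test of dye bias that differs between arrays replaced earlier versions: a draw of sets of replicates, which excluded that bias for both lists but whose highest possible value lay so near the real one that it could hardly come out otherwise, and a t test, which left it open over the lists but not for each list by itself. The exchange of signs also counts lists that differ between pools, which raises its share over any list. For the pool differences, the replicate means had been seen and the share for a single list estimated by eye before the share over any list was chosen, so both shares are given.

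In 33 groups of 6 values, 3 values lay far from the other 5 by Dixon's criterion, which chance meets in about 1 of 20 groups. The skeletal muscle mean of male IS21FE replicate 1 was -0.31, with the other IS21FE replicates between -0.14 and -0.074. The liver mean of female IS21SE replicate 2 was -0.29, with the other IS21SE replicates between 0.21 and 0.42; a wrong label of an array in that replicate was not tested. The SD of log ratios on the array of female IS21SE replicate 2 with the treated RNA in Cy5 was 0.714, with the other arrays of that group between 0.823 and 0.835.

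Camera on the differences themselves called 10 list differences over 29 lists and 3 contrasts, and none held with an estimated correlation. For IS21FE, female minus male, erythroid genes differed by -0.14 (-0.058 in females, 0.079 in males; adjusted p = 0.00963), matrix genes by -0.070 (-0.10 and -0.034; adjusted p = 0.0371) and ribosomal genes by -0.082 (-0.080 and 0.0018; adjusted p = 1.98e-05), against an adjusted p of 0.948 with an estimated correlation. Without male replicate 3 the erythroid difference was -0.030 and the matrix difference 0.0038, and neither passed; without female replicate 3 neither passed (-0.14 and -0.078), and the matrix list did not pass without female replicate 2 (-0.036) or male replicate 1 (-0.11). The erythroid difference was -0.24 without male replicate 2, and the ribosomal difference was -0.043 and -0.14 without female replicates 1 and 2. With the treated RNA in Cy5 alone the ribosomal difference was 0.0020 (adjusted p = 0.216) and the matrix difference -0.032 (adjusted p = 0.141). With the control RNA in Cy5 alone the erythroid difference was -0.037 and the matrix difference -0.11, and neither passed. Without the 3 arrays that resembled each other none of the 3 passed (ribosomal -0.081, adjusted p = 0.103; erythroid -0.14; matrix -0.17), and with a term for them the erythroid difference was -0.086 and did not pass.

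For IS21SE, female minus male, heart muscle genes differed by -0.47 (-0.064 and 0.41; adjusted p = 0.000189), liver genes by -0.17 (0.12 and 0.30; adjusted p = 0.0122) and ribosomal genes by -0.062 (-0.0062 and 0.056; adjusted p = 0.0414), against an adjusted p of 0.937 with an estimated correlation. Without female replicate 2 the liver difference was 0.032, and without male replicate 1 it was -0.11 (adjusted p = 0.125). The ribosomal difference did not pass without female replicate 2 (-0.070) or 3 (-0.048) or male replicate 2 (-0.036) or 3 (-0.047). Without male replicate 2 the heart muscle difference was -0.31 (adjusted p = 0.0243), without female replicate 1 the liver difference was -0.31, and without male replicate 1 the ribosomal difference was -0.10. With the control RNA in Cy5 alone neither the liver difference (-0.16) nor the ribosomal difference (-0.076) passed, and with the treated RNA in Cy5 alone the ribosomal difference did not (-0.048). Nor did either pass with a term for the 3 arrays that resembled each other (-0.15 and -0.059) or without them (-0.11 and -0.055).

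Between IS21FE and IS21SE, over both sexes, endothelium genes differed by -0.15 (-0.078 and 0.071; adjusted p = 0.0329), heart muscle genes by -0.21 (-0.043 and 0.17; adjusted p = 0.0329), ribosomal genes by -0.064 (-0.039 and 0.025; adjusted p = 0.00951) and skeletal muscle genes by -0.16 (-0.14 and 0.020; adjusted p = 0.00951), against an adjusted p of 0.971 with an estimated correlation. Without male IS21SE replicate 2 these 4 differences were -0.16, -0.13, -0.051 and -0.14, and none passed. The endothelium difference also lost its call without female IS21FE replicates 1 (-0.14) and 2 (-0.11), male IS21FE replicates 1 (-0.12) and 2 (-0.13), female IS21SE replicate 2 (-0.13) and male IS21SE replicate 3 (-0.12). The heart muscle difference lost it without female IS21FE replicate 1 (-0.18), male IS21FE replicates 1 (-0.18) and 2 (-0.15) and female IS21SE replicate 3 (-0.15), the ribosomal difference without female IS21FE replicates 1 (-0.045) and 3 (-0.055) and male IS21FE replicate 2 (-0.051), and the skeletal muscle difference without male IS21FE replicate 1 (-0.13) and female IS21SE replicate 2 (-0.12). With the treated RNA in Cy5 alone the endothelium (-0.12) and ribosomal (-0.027) differences did not pass, and with the control RNA in Cy5 alone the endothelium (-0.15), heart muscle (-0.18) and skeletal muscle (-0.19) differences did not. Without the 3 arrays that resembled each other the endothelium (-0.17), heart muscle (-0.20) and ribosomal (-0.068) differences did not pass, with a term for them the endothelium difference did not (-0.16), nor did it on ranks (-0.15).

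The liver and heart muscle lists were positive in male IS21SE pools (means 0.30 and 0.41). A dye bias common to all arrays cancels in the mean of both orientations of a replicate, so it cannot give these means. All 3 replicates were positive in both orientations for the liver list and 3 for the heart muscle list. These signs are therefore no further test of a common bias. Both lists were picked for their positive means, which makes positive values in both orientations more likely. A dye bias that differs between arrays was not tested for these lists. Differences between pools whatever the strategy stayed open: of the 220 sets of 3 of the 12 replicates, a share of 0.805 gave some list a mean as far from 0, in units of its SD, as the liver list, and 0.364 as the heart muscle list. For each list by itself the shares were 0.186 and 0.0136. An effect of IS21SE in male embryos remains an open explanation too, since the pools of the strategy are also the pools of certain sows. The liver mean was also positive, at 0.11 or more, in the other comparisons of a given sex with control, IS21FE included. The liver list was not called for the difference between strategies.

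The ribosomal list was negative in female IS21FE pools (mean -0.080). Its mean was 0.051 on the arrays with the treated RNA in Cy5 and -0.21 on those with the control RNA in Cy5, and a dye bias common to all arrays cancels in the mean of both. The dye term is therefore no further test of a common bias. With a dye term and a term for the 3 arrays that resembled each other the mean was -0.072 (camera adjusted p = 0.0365 with the preset correlation). This argues against those arrays as the whole cause, although without them the mean was -0.079 with an adjusted p of 0.0556. A dye bias that differs between arrays does not cancel. When the signs of the 6 arrays were exchanged in all 64 ways, a share of 0.375 gave some list a mean as far from 0, in units of the list's SD of the differences between orientations, and 0.156 for this list by itself, so that bias stayed open. An effect of IS21FE in female embryos was not separated from it.

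The skeletal muscle list was negative in IS21FE pools of both sexes (mean -0.14, negative in 6 of 6 replicates). A dye bias common to all arrays cancels by construction in these replicate means, so a dye term is no further test of it. With a dye term and a term for the 3 arrays that resembled each other the mean was -0.19. Its camera adjusted p was 1.83e-06 with the preset correlation, whereas in the main fit the list had 0.945 with an estimated correlation. A dye bias that differs between arrays stayed open: of the 4096 sign exchanges of the 12 arrays a share of 0.44 gave some list a mean as far from 0, in the same units, although 0.0107 for this list by itself. A share of 0.0725 of the 924 sets of 6 of the 12 replicates gave some list a mean as far from 0, against 0.00433 for this list by itself, so differences between pools whatever the strategy stayed open, and so does an effect of IS21FE.

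Genes with an unadjusted p under 0.05 were counted again with the sign of whole replicates or their group exchanged, since 0 genes passed an adjusted p. For the 4 groups against control there are 4 splits each, too few for a share under 0.05: the real count was 783 and the highest other 548 in female IS21FE (1 of 4 splits as large), 630 and 830 in male IS21FE (4 of 4), 459 and 717 in female IS21SE (2 of 4), and 1154 and 616 in male IS21SE (1 of 4). For the difference between sexes the 10 splits are too few as well: 500 and 687 for IS21FE (3 of 10), and 665 and 505 for IS21SE (1 of 10). For the mean of both sexes chance is not excluded: 5 of 32 splits gave as many as the 665 of IS21FE (highest other 763), and 3 of 32 as many as the 701 of IS21SE (highest other 1130). Nor is it for the difference between strategies, with 384 genes, where 29 of 100 drawn splits gave as many and the highest gave 907.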

How the results depend on the processing

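Of the alternatives, the 27 lists, genes with 1 measured replicate, replicates with 1 measured array, both settings for the 3 arrays that resembled each other, single dye orientations and left-out replicates for lists, and list tests of differences were chosen after seeing the data. The cause was not tested for the moves below unless fewer arrays, replicates or genes give it by construction, and no signal over background is held, so what it limits could not be tested. Gene counts stayed at 0 in all 9 contrasts with centring, scaling, no blanks (6606 genes), genes with the smallest ratios left out (8926 genes kept), the median of probes, array weights, robust moderation, groups fitted apart and a threshold of 0.10. The replicate block also left 0 genes and 0 probes, as a random block (correlation 0.0647) and as a fixed block for the differences between sexes. Counts at an unadjusted p under 0.05 did move. In female IS21FE, male IS21FE, female IS21SE and male IS21SE, array weights gave 1845, 506, 817 and 1575 genes. Groups fitted apart gave 963, 446, 507 and 913 in the same order. The weights were estimated from the same arrays. Of 2744 refits of 140 named gene values, 2713 kept direction and side of the threshold, 14 passed it and 17 turned sign. That share does not measure robustness. In the main fit 0 genes passed, and most of these genes were chosen for a small p. Centring, scaling and robust moderation left ratios that correlated with the main ones at r = 1, so signs could hardly turn there.

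Single arrays with a dye term, where the correlation between the 2 arrays of a replicate was -0.0452 so that they count as nearly independent, called 1 gene in female IS21FE, 4 in male IS21SE, 2 for the mean of IS21FE and 1 for its difference between sexes, and 1 probe in female IS21FE and 7 in male IS21SE. An unadjusted p under 0.05 with at least 1.5-fold gave 275, 405, 205 and 488 genes in female IS21FE, male IS21FE, female IS21SE and male IS21SE, 119 and 145 for the means of IS21FE and IS21SE, 323 and 415 for their differences between sexes and 129 between strategies. Replicates with 1 measured array gave 1 gene and 7 probes in male IS21FE and 1 probe in male IS21SE. Genes or probes with 1 measured replicate added 1 probe in male IS21FE, and a threshold of 0.10 added 1 probe in male IS21SE. Leaving out replicates gave 0 to 3 genes and 0 to 1 probes in male IS21SE, and 0 in the other contrasts.

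With the treated RNA in Cy5 alone, male IS21FE had 8 genes and 3 probes and male IS21SE 5 genes and 21 probes. SCNN1G in female IS21SE turned to 0.021, GKN2 in male IS21SE to -0.60 and HOOK1 in the sex difference of IS21FE to 0.13. RPLP2 (0.091) and RPS21 (0.080) in female IS21FE, HOXD13 in male IS21FE (-0.78), and RPL6 (0.050) and RPS19 (0.052) in the mean of IS21FE also turned. The lists past the threshold numbered 1 in female IS21FE, 5 in male IS21FE, 4 in male IS21SE and 2 for the mean of IS21SE. In female IS21FE the matrix mean was -0.091, the muscle mean -0.13 and the ribosomal mean turned to 0.051; for the mean of IS21FE the matrix mean was -0.075 and the ribosomal mean turned to 0.050.

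With the control RNA in Cy5 alone, male IS21FE had 1 gene and 3 probes, female IS21SE 2 probes, the sex difference of IS21FE 1 gene and the difference between strategies 1 gene. SKAP1 turned to 0.41 in male IS21SE and 0.14 in the mean of IS21SE, CALCB to -0.026 in that mean, RPLP1 to 0.0061 in female IS21FE, and COL1A2 (0.0090) and DCN (0.024) in the mean of IS21FE. List counts were 1 in female IS21FE, 0 in male IS21FE, 1 and 0 for the means of IS21FE and IS21SE, 1 for the sex difference of IS21FE and 1 between strategies. Lists that lost their call were matrix (-0.12) and muscle (-0.065) in female IS21FE, muscle in male IS21FE (-0.18), matrix (-0.065) and muscle (-0.12) in the mean of IS21FE and liver in the mean of IS21SE (0.22).

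With a term for the 3 arrays that resembled each other, male IS21SE had 5 genes and its sex difference 1, and the genes that the dye term alone called in female IS21FE, the mean of IS21FE and its sex difference fell to 0. List counts were 6 in female IS21FE, 2 in male IS21FE, 1 in female IS21SE, 3 for the mean of IS21SE, and 5 and 1 for the sex differences of IS21FE and IS21SE. The ribosomal mean was -0.035 in the mean of IS21FE and did not pass, and PAX3 in female IS21FE turned to -0.16. Without those arrays these 3 counts were 0 too, male IS21SE had 3 genes, list counts were 2 in male IS21FE, 1 in female IS21SE, 3 for the mean of IS21SE, 0 and 1 for the sex differences and 1 between strategies. The ribosomal mean did not pass in female IS21FE (-0.079) or the mean of IS21FE (-0.039), PAX3 turned to -0.12 and RPLP1 to 0.014.

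With an estimated correlation 0 lists passed in any contrast. List means do not move under it: matrix -0.10, ribosomal -0.080 and muscle -0.094 in female IS21FE, muscle -0.19 in male IS21FE, heart muscle 0.41 and liver 0.30 in male IS21SE, matrix -0.069, ribosomal -0.039 and muscle -0.14 in the mean of IS21FE, and liver 0.21 in the mean of IS21SE. On ranks, 2 lists passed in male IS21FE.

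Without each replicate in turn, list counts ran from 1 to 4 in female IS21FE, 0 to 4 in male IS21FE, 0 to 1 in female IS21SE, 2 to 5 in male IS21SE, 2 to 5 for the mean of IS21FE, 0 to 2 for the mean of IS21SE, 1 to 6 and 1 to 5 for the sex differences of IS21FE and IS21SE and 0 to 5 between strategies. Means ran from -0.13 to -0.069 (matrix) and -0.10 to -0.088 (muscle) in female IS21FE, -0.23 to -0.13 (muscle) in male IS21FE, 0.24 to 0.52 (heart muscle) in male IS21SE, -0.11 to -0.049 (matrix) and -0.068 to -0.020 (ribosomal) in the mean of IS21FE, 0.14 to 0.31 (liver) in the mean of IS21SE and -0.31 to 0.032 (liver) in its sex difference.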

Other observations

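The hypothesis that list means reflect the RNA pools rather than labelling was tested after the list values had been seen. If it holds, the mean of a list from the arrays with the treated RNA in Cy5 should correlate with that from the arrays with the control RNA in Cy5 over the 12 replicates. Among 29 lists the correlation passed for 2. For the liver list Pearson's r was 0.801 (permutation p = 0.002, adjusted p = 0.029) and Spearman's rho 0.804 (adjusted permutation p = 0.0407), and r was 0.858 without the 2 replicates farthest from the median, 0.75 in the 6 female and 0.948 in the 6 male replicates. For the heart muscle list r was 0.937 (permutation p = 6e-05, adjusted p = 0.00174) and rho 0.888 (adjusted permutation p = 0.00783), and r was 0.859 without the 2 farthest replicates, 0.833 in females and 0.982 in males. These lists may thus differ between pools, in both strategies and the controls they were set against, through the share or state of liver and heart in the pooled embryos; no tissue was weighed or counted in the sources used here, and female and male pools came from the same sows, so the 12 replicates are not fully independent. The other 27 lists did not pass, and the HOX list had r = -0.609 (adjusted permutation p = 0.159).

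The liver list was not called in IS21FE pools, where single replicates reached 0.58 (male replicate 1) and 0.44 (female replicate 1) and others -0.20 (male replicate 2) and -0.046 (female replicate 2). Its mean was nevertheless positive in every comparison of a given sex with control, from 0.11 to 0.30. In male IS21FE pools the mean was 0.11, with the lowest camera adjusted p of the lists not called there (0.0825). Nor was the liver list called for the difference between strategies, so its positive mean is not particular to IS21SE. Female and male pools with the same replicate number were correlated across 18481 probes, after the mean of each group had been removed. For numbers 1 to 3, r was 0.217, 0.101 and 0.0605 for IS21FE and 0.0115, -0.0165 and -0.0308 for IS21SE. The male pool of the same number had the highest r for female IS21FE pools 1 and 2, but not for pool 3 or any IS21SE pool. Probes are not independent replicates.

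The 3 arrays that resembled each other had at least 38916 measured probes, against at most 38572 on any other array, and an SD of at most 0.7138, against at least 0.7153. Other pairs of arrays had a median rho of 0.108. The highest, 0.603 as deposited, was between female IS21SE replicate 3 with the treated RNA in Cy5 and female IS21SE replicate 2 with the control RNA in Cy5, which are opposite orientations of different replicates. Whether an array of these replicates carries a wrong label was not tested.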
